A study of Mus musculus with 2 samples.

How the data were processed

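H3K27ac was measured by chromatin immunoprecipitation and sequencing in neural tube of B6 mouse embryos on embryonic day 14.5, in 2 biological replicates of 1 group. Replicate 1 came from 24 embryos and replicate 2 from 34, with a fragment size range of 300 to 500 bp, per the labels' protocols. There was no second group, so no test between groups was made. Results rest on 4 peak lists in the narrowPeak layout on mm10. Per the submitters' file records, each replicate's own list was called on that replicate's alignments, the pooled list on the alignments of both, and the replicated list was derived from the other 3. The rule that selected replicated peaks is not given in the sources used here, nor are the aligner, the peak caller and their versions. The same records list 2 further input files for replicate 1's own list and 1 for replicate 2's, of a kind they do not state, so the 2 lists differ in the number of their inputs.

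The deposited fold of each peak (column 7, a ratio) was computed by the authors, and the records do not state what it is relative to. The deposited −log10 p and −log10 q values of each peak (columns 8 and 9) were likewise computed by the authors. Column 10 gives the summit. Folds were tested only within a list. Between the replicates' own lists they were correlated by rank across overlapping peaks, and values of several lists are printed together without a test. No read counts are in the lists, so depth per sample and the counting error of a fold are unknown, and the absence of a peak is not a measured absence of acetylation. Alignments, signal tracks and controls were not used here.

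Peaks on chromosomes 1 to 19, X and Y were kept. The main peak set was the replicated list. Genes and TSSs came from GENCODE vM21 and sequence from GRCm38.p6, the assembly that mm10 denotes. A promoter peak overlaps the region within 1000 bp of any annotated TSS of a protein-coding gene, and other peaks are distal. Genes were taken by symbol, which gave 21911. Distal peaks were assigned to the gene of the nearest TSS, and a gene's territory is the sequence nearest to its TSSs. CpG content is the observed over expected CpG within 500 bp of the gene's 5' end, which can lie away from the TSS that has the peak. Coordinates are 1-based on mm10.

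Overlap of the replicates (at least 1 bp) and the promoter share were compared with 1000 circular shifts within chromosomes (one-sided). Folds of promoter and distal peaks were compared by permuting log2 fold across peaks (100000 resamples, two-sided). Gene lists written before the data were examined (31 lists, 7 to 20 genes each apart from 1134 olfactory receptor genes) were tested for promoter peaks by Fisher's exact test, two-sided, against all other protein-coding genes. Their distal peaks were tested against 10000 random lists matched on decile of territory length. Hox genes were compared with forebrain transcription factor genes, and Hox paralogues 1 to 9 with 10 to 13, by Fisher's exact test. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. Distal peaks within 10000 bp were joined and ranked by the sum of fold times length, with no test. Motif copies were counted in distal peaks and in windows of equal length, 5000 to 50000 bp away and off all peaks. Of several random windows the closest in GC content was taken, and peaks with none within 2 percentage points were left out. Intervals come from 1000 bootstrap draws over chromosomes. Genes and peaks are not replicates, and p-values across them describe these pools only.

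Genes are named by a rule. From each list the 3 members with the highest promoter fold are named and up to 3 without a peak in alphabetical order. For lists of other cell types or controls all members with a peak are named where 3 or fewer have one. The 10 highest promoter folds and the 20 highest stitched regions follow, then all Hox genes and the 15 genes with the most distal peaks. The last 2 groups, and the members with the most distal peaks of 6 lists, were added after their values were seen.

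Alternatives were TSS windows of 500 and 2500 bp, the 5' end of the gene alone, the pooled list, the 50% of peaks of highest fold, a −log10 q of at least 5, each replicate's own list in place of the replicated list, random lists matched on CpG content, unmatched lists and windows, other overlaps, other stitching distances (5000 and 20000 bp), other rankings and 200 bp around the summit. Gene lists, the tests of the main results and the naming rule were fixed before the data were examined, apart from the names added later, as given above. The alternatives were too, except 2 added later: peaks found in both replicates' own lists, and each list without its member with the most distal peaks. Tests of the flagged results and other observations that were chosen later are named with them.

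The scripts were tested on simulated data. Overlapping pairs were those of bedtools in 100% of 1016 pairs. Simulated promoter lists were called in 93.2% when raised to a share of 95% (13 to 15 genes), 93% when lowered to 5% (10 to 18 genes) and 1.15% when unchanged, over 21911 genes. Distal lists were called in 72% when raised 4 times and 1% when unchanged, over the same genes. Simulated promoter shares were the same for all unchanged genes, whereas real ones varied with CpG content. Simulated distal counts followed a Poisson distribution with a mean set by territory length. Real counts were more uneven, as 15679 genes had none and Camta1 had 108. The 72% may thus overstate the power on the real data. In 20 simulated genomes, motif copies in peaks above those in windows came to 100.2% of the planted copies. Of 150 intervals of motifs that were not planted, 10% excluded 0, where 5% is expected, so the bootstrap intervals are too narrow. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0 and matplotlib 3.10.9, and bedtools 2.31.1.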

Results

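The series measured acetylation of lysine 27 on histone H3 (H3K27ac), a mark of active promoters and enhancers, by chromatin immunoprecipitation and sequencing. The tissue was neural tube, dissected from mouse embryos of the B6 strain on embryonic day 14.5. Which levels of the body axis it spanned is not given in the sources used here. There was 1 group with 2 biological replicates. Replicate 1 was a pool of 24 embryos and replicate 2 a pool of 34, and each pool held male and female embryos. With no second tissue, stage or antibody, the design asks which promoters and distal regions carried the mark in this tissue and how far 2 pools of embryos gave the same regions. Values come from 4 peak lists on the mm10 genome: 1 for each replicate, 1 called on both replicates together (the pooled list) and 1 replicated list derived from the other 3. The fold printed for a peak is the authors' own value for that peak, and it ranks peaks only within its own list. Sequencing depth is unknown, because the lists hold no read counts.

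The replicated list held 41088 peaks on chromosomes 1 to 19, X and Y, with a median width of 560 bp and a covered length of 33.9 Mb, 1.24% of the genome. Their folds ran from 1.75 to 60.2 with a median of 4.23. Each of these peaks was identical to a peak of the pooled list, which held 60491. Replicate 1's own list held 61504 peaks over 29.7 Mb and replicate 2's held 68099 over 36.7 Mb, a mean of 64801.5 ± 4663 peaks (SD, n = 2) and of 33.2 ± 4.99 Mb. The median fold was 3.59 in replicate 1 and 3.97 in replicate 2.

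Stronger acetylated regions were shared between the pools more often than weaker ones. Of the replicate 1 peaks, 63.3% overlapped a replicate 2 peak by at least 1 bp, against a mean of 2.61% after circular shifts within chromosomes. Of the replicate 2 peaks, 52.3% overlapped a replicate 1 peak, against 2.33% after shifts. Both shares passed all 1000 shifts (one-sided permutation p = 0.001, the smallest possible). Shared peaks of replicate 1 had a median fold of 4.08, and those without a partner 3.2. In replicate 2 the medians were 5.06 and 3.35. Shared peaks were also wider, with medians of 410 against 222 bp in replicate 1 and 532 against 241 bp in replicate 2. A wider peak is more likely to overlap another by 1 bp. Among the 20000 peaks of smallest p in each list, the overlap was 80.7% and 74.5%. With both lists cut to a −log10 q of at least 5, it was 89.1% for replicate 1's 16940 peaks and 63.6% for replicate 2's 22561. Replicate 2's peaks were thus set against a shorter list, which limits their share. Requiring a reciprocal overlap of 50% over all peaks lowered the shares to 36.2% and 32.7%. Across 38939 overlapping peaks the folds of both lists had a Spearman rho of 0.63. This is a correlation across peaks, which are not independent replicates. Of the replicated peaks, 76.6% overlapped a peak of each replicate's own list and 1.59% overlapped neither.

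Promoters carried a large part of the mark. Of the replicated peaks, 14909 (36.3%) lay within 1 kb of a transcription start site (TSS) of a protein-coding gene, against a mean of 5.31% after shifts (one-sided permutation p = 0.001, the smallest possible). In the replicates' own lists the share was 30.5% and 28.0%, a mean of 29.2 ± 1.75% (SD, n = 2). Promoter peaks had a geometric mean fold of 7.40 and distal peaks of 4.14, a ratio of 1.79 (two-sided permutation p = 1e-05 across peaks, the smallest possible). Their median widths were 836 and 472 bp, so that promoter peaks made up 48.2% of the covered length. The middle of 38.6% of all replicated peaks lay in an intron, of 20.9% between genes and of 4.26% in an exon away from promoters. Distal peaks lay a median of 26.4 kb from the nearest protein-coding TSS (quartiles 8.73 and 72.8 kb).

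In all, 11557 of 21911 protein-coding genes (52.7%) had a promoter peak. The share rose from 4.29% in the lowest decile of genes by CpG content of the promoter to 94.3% in the highest. The 10 highest promoter folds were as follows. The peak shared by Zc3h6 and Gm10762 (chromosome 2, 128966695 to 128968803) had a fold of 60.2. It was followed by Klf7, a Krüppel-like factor expressed in neurons, at 59.9 (chromosome 1, 64118015 to 64123338). Next came Zc3h4 (58.6), the transcription factor gene Sp3 (57.9), the arrestin-domain gene Arrdc3 (56.7) and Pcbp1, a poly(C)-binding protein (55.5). Epc1 had 53.5, the histone methyltransferase genes Kmt5b and Kmt2e had 53.4 and 51.1, and Rhof had 48.3. At Rhof the value came from a wide peak of 7429 bp in the combined lists. The promoter had no peak in replicate 1's own list and a fold of 6.83 in replicate 2's.

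Genes used by all neurons were acetylated throughout. All 18 pan-neuronal genes had a promoter peak, against 52.7% of other genes (adjusted p = 0.000117, Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 31 gene lists, as for all lists here). The highest folds were at Rbfox3, the neuronal nuclear antigen NeuN (29.5), at Map2, a dendritic microtubule protein (24.2), and at Mapt, which encodes tau (22.4). The replicates' own lists gave 21.2 and 30.8 at Rbfox3, 14.2 and 20.9 at Map2, and 16.2 and 23.5 at Mapt. All 10 genes of inhibitory transmission had a peak (adjusted p = 0.00625, Fisher's exact test). Gphn, the scaffold of inhibitory synapses, had a fold of 21.4, and the GABA-synthesising enzymes Gad2 and Gad1 had 17.5 and 13.5. Of the 14 neural progenitor genes, 13 had a peak (adjusted p = 0.00625, Fisher's exact test), led by the RNA-binding protein Msi1 (40), the Notch target Hes5 (14.8) and the filament gene Vim (13.1). Sox3 was the member without one. In the own lists of replicates 1 and 2 Hes5 had 8.08 and 7.72, below Vim (9.27 and 12.7). Here and below, a gene without a peak has none in the replicated list. Of the genes so named, Lhx3, Aqp4, Runx1 and Erg had a promoter peak in both replicates' own lists. Replicate 1's own list alone had one at Barhl1, Olig1, Avil, Ntrk1, Col1a2, Col9a1 and Epor. Replicate 2's alone had one at Sox3, Dbx1, Foxa2, Lhx2, Evx1, Gata3, Chat, Hoxb1, Hoxc13, Egr2, Cdh5, Emcn, B2m and Cdk1. Of 14 housekeeping genes, 13 had a peak (adjusted p = 0.00625, Fisher's exact test). Actb had 46.8, Ywhaz 46.6 and Eef1a1 31.7, and B2m had none. Counting the 5' end of the gene alone ended the housekeeping call (adjusted p = 0.062, Fisher's exact test; 0.000961 to 0.125 over the alternatives). Against random lists matched on CpG content, the pan-neuronal and inhibitory lists stayed above (adjusted p = 0.00155 and 0.00852, permutation). The neural progenitor and housekeeping lists did not pass (adjusted p = 0.105 and 0.125, permutation).

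**Figure D1:**
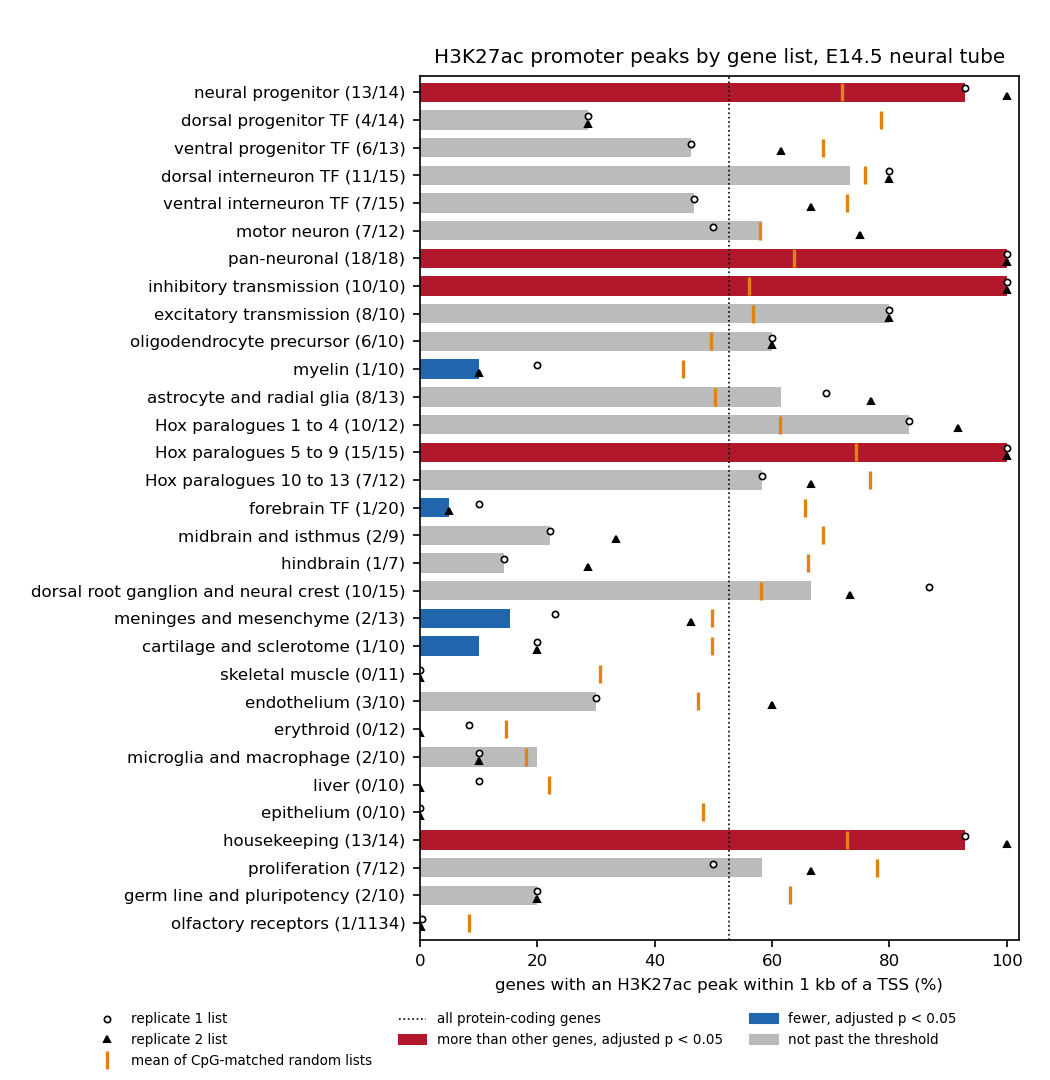
Percentage of the genes of each list with an H3K27ac peak within 1 kb of a TSS (horizontal axis) for the 31 gene lists (vertical axis, with members with a peak and all members). Bars show the replicated list (red higher and blue lower than other genes, grey without a call), circles and triangles the own lists of replicates 1 and 2, orange ticks the mean of random lists matched on promoter CpG content and the dotted line all protein-coding genes (52.7%). Pan-neuronal genes stand at 100% and forebrain transcription factor genes at 5%.

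The transcription factors that set up neuron classes were marked unevenly, and their shares did not pass the test against all other genes. Of 15 dorsal interneuron factors, 11 had a promoter peak (adjusted p = 0.178, Fisher's exact test). Lbx1 had a fold of 21.2, Lmx1b 12.7 and Tlx3 11.9, and Barhl1, Lhx2 and Lhx9 were among those without. Of 15 ventral interneuron factors, 7 had one (adjusted p = 0.797, Fisher's exact test). The LIM-homeodomain genes Lhx1 and Lhx5 had 10.9 and 10.8 and Foxp2 had 4.52, while Evx1, Gata2 and Gata3 had no peak. Of 12 motor neuron genes, 7 had one (adjusted p = 0.797, Fisher's exact test). Foxp1, a factor of limb motor columns that other tissues also express, had 33.5, Isl1 4.45 and Ret 3.81. Aldh1a2, Lhx3 and Chat, which encodes the acetylcholine-synthesising enzyme, had none. Lhx3 had 3.29 and 3.32 in the own lists of replicates 1 and 2.

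Progenitor domain factors did not pass the test against all other genes either. Of 14 dorsal progenitor factors, 4 had a peak (adjusted p = 0.163, Fisher's exact test). These included the proneural genes Ascl1 (9.63) and Neurog2 (4.04) and the roof-side factor Pax3 (3.70). Atoh1, Gsx1 and Gsx2 had none. Lists matched on CpG content had a mean share of 78.6%, and against them the dorsal progenitor list was lower (adjusted p = 0.00155, permutation). It was also lower when the 50% of peaks with the highest fold were used (adjusted p = 0.00682, Fisher's exact test). Over all alternatives its adjusted p ran from 0.00155 to 0.255. Of 13 ventral progenitor factors, 6 had a peak (adjusted p = 0.797, Fisher's exact test), with Irx3 at 7.54 and both Nkx6-1 and the signalling gene Shh at 4.57. Dbx1, Dbx2 and Foxa2 had none.

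Among the other lists of the tissue, 8 of 10 genes of excitatory transmission had a peak (adjusted p = 0.169, Fisher's exact test). The vesicular glutamate transporter gene Slc17a6 had 22.2, and the receptor genes Gria2 and Grin2b had 15.9 and 13.6. The transporter genes Slc17a7 and Slc17a8 had none. Of 13 astrocyte and radial glia genes, 8 had one (adjusted p = 0.730, Fisher's exact test), led by Nfib (28.5), the glutamine synthetase gene Glul (22) and Nfia (13.1). Aldh1l1, Aqp4 and Gfap, the astrocyte filament gene, had none. Aqp4 had 3.29 and 3.97 in the own lists of replicates 1 and 2. Of 10 oligodendrocyte precursor genes, 6 had one (adjusted p = 0.797, Fisher's exact test), with Bcas1 at 4.37, Sox10 at 4.23 and Ptprz1 at 4.13, and Cspg4, Gpr17 and Olig1 without. Of 10 myelin genes, Cnp alone had a peak (fold 4.27), and the list was lower than other genes (adjusted p = 0.0200, Fisher's exact test). Cldn11, Mag and Mbp, which encodes myelin basic protein, had none. In replicate 1's own list 2 myelin genes had a peak and the call was lost (adjusted p = 0.0872, Fisher's exact test, the highest of alternatives that start at 0.0167). Of 12 proliferation genes, 7 had a peak (adjusted p = 0.797, Fisher's exact test), led by Birc5 (15.5), Mcm2 (7.19) and Mcm5 (6.47), and Ccnb1, Ccnd2 and Cdk1 had none.

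Markers of muscle, blood, liver and epithelium were unmarked in the replicated list. No peak lay at a promoter of 11 skeletal muscle genes (adjusted p = 0.00135), 12 erythroid genes (adjusted p = 0.000766), 10 liver genes (adjusted p = 0.00215) or 10 epithelial genes (adjusted p = 0.00215, Fisher's exact test for all 4). Acta1, Actc1 and Ckm were among the muscle genes, Alas2, Epor and Gata1 among the erythroid, Afp, Ahsg and Alb among the liver and Cdh1, Epcam and Esrp1 among the epithelial genes. Erythroid and liver promoters are poor in CpG, and against CpG-matched lists those calls ended (adjusted p = 0.317 and 0.248, permutation). Of 13 genes of meninges and mesenchyme, Foxc1 (5.96) and the collagen gene Col3a1 (3.18) had a peak (adjusted p = 0.0214, Fisher's exact test). Col1a1, Col1a2 and Dcn had none. This call depended on the list used. The replicates' own lists marked 3 and 6 of these genes (adjusted p = 0.0872 and 0.646, Fisher's exact test), and with the pooled list the adjusted p was 0.0556, within a range of 0.00506 to 0.646 over the alternatives. Of 10 cartilage and sclerotome genes, Col2a1 had a peak (5.77) and Acan, Col9a1 and Comp had none (adjusted p = 0.0200, Fisher's exact test). Each replicate's own list marked 2 of them, and the adjusted p was then 0.0872 and 0.098 (Fisher's exact test), the highest of alternatives that start at 0.0167.

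Endothelial, microglial, neural crest and germ line lists did not pass the test with the replicated list. In 3 of 10 endothelial genes a peak was listed, namely Cldn5 (3.72), Flt1 (3.53) and the VEGF receptor gene Kdr (3.53), and Cdh5, Emcn and Erg had none (adjusted p = 0.279, Fisher's exact test). Erg had 3.29 and 2.70 in the own lists of replicates 1 and 2. Replicate 1's own list marked 3 endothelial genes and replicate 2's marked 6. The list was lower with the 50% of peaks of highest fold (adjusted p = 0.00682) and with a −log10 q of at least 5 (adjusted p = 0.00527, Fisher's exact test for both), over alternatives that reach 1. Of 10 genes of microglia and macrophages, Tmem119 (4.92) and Csf1r (3.10) had a peak, and Aif1, C1qa and Cx3cr1 had none (adjusted p = 0.0992, Fisher's exact test). Csf1r had no peak in either replicate's own list. The microglial list was lower in 6 of 10 alternatives, among them replicate 2's and replicate 1's own lists (adjusted p = 0.0167 and 0.0193, Fisher's exact test). Against CpG-matched lists it was not (adjusted p = 1, permutation). Of 15 genes of dorsal root ganglion and neural crest, 10 had one (adjusted p = 0.404, Fisher's exact test), led by the neurotrophin receptor gene Ntrk2 (17.8), Tfap2a (12.4) and Ntrk3 (12.3). Avil, Ntrk1 and Runx1 had none. Runx1 had 2.24 and 3.97 in the own lists of replicates 1 and 2. The lists of the neural tube also hold 4 of these 15 genes. Replicate 1's own list marked 13 of them, and the list was then higher than other genes (adjusted p = 0.0394, Fisher's exact test, the lowest of alternatives that reach 0.886). Of 10 germ line and pluripotency genes, Tex14 (14.5) and Dazl (5.45) had a peak, and Ddx4, Dppa3 and Mael had none (adjusted p = 0.0992, Fisher's exact test). The olfactory receptor list was lower. Of its 1134 genes 1 had a peak, Olfr94 (5.32), against 55.6% of other genes. Olfr1, Olfr10 and Olfr1000 were among those without, and the p-value of the exact test was too small for floating-point numbers (adjusted p = 0.00155 against CpG-matched lists, permutation).

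Hox promoters were mostly acetylated and promoters of forebrain factors mostly were not. Of 39 Hox genes, which pattern hindbrain and spinal cord, 32 (82.1%) had a promoter peak. Of 20 transcription factor genes of the forebrain, 1 did (5%), namely Satb2 with a fold of 7.19 (adjusted p = 1.57e-08, Fisher's exact test, two-sided, adjusted over 2 comparisons). Arx, Dlx1 and Dlx2 were among the 19 without. The forebrain list was lower than all other genes (adjusted p = 0.000117, Fisher's exact test) and lower than CpG-matched lists, whose mean share was 65.6% (adjusted p = 0.00155, permutation). The midbrain and isthmus list had 2 of 9 genes with a peak, En1 (4.23), which also marks a class of spinal interneurons, and Gbx2 (4.19), and En2, Fgf17 and Fgf8 had none (adjusted p = 0.154, Fisher's exact test). The hindbrain list had 1 of 7, Mafb (6.44), and Atoh1, Egr2 and Fev had none (adjusted p = 0.0994, Fisher's exact test). Against CpG-matched lists both were lower (adjusted p = 0.00852 and 0.0259, permutation), as was the germ line list (adjusted p = 0.0234, permutation).

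Within the Hox clusters the mark covered paralogues 5 to 9 completely. All 15 of them had a peak (adjusted p = 0.000626, Fisher's exact test; 0.0281 against CpG-matched lists, permutation). Of 12 genes of paralogues 1 to 4, 10 had one (adjusted p = 0.0867, Fisher's exact test; 0.0346 to 0.217 over the alternatives, with a call in 4 of 10), and of 12 genes of paralogues 10 to 13, 7 had one (adjusted p = 0.797, Fisher's exact test). Paralogues 1 to 9 together had 25 of 27, more than paralogues 10 to 13 (adjusted p = 0.0197, Fisher's exact test). With the pooled list that adjusted p was 0.0601. Neighbouring genes share wide peaks, so that the 32 marked promoters lay under 22 distinct peaks and the genes were not independent.

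In the Hoxb cluster on chromosome 11 a single peak of 79.3 kb, the widest of the replicated list (96268263 to 96347573, fold 45.1), covered the promoters of Hoxb3, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8 and Hoxb9. The next peak covered Hoxb2 (38.4), and Hoxb1 and Hoxb13 had none. In the Hoxa cluster on chromosome 6 a peak of 17.3 kb (52210922 to 52228191, fold 32.3) touched TSSs of Hoxa3, Hoxa7 and Hoxa9. Hoxa2 had 27.9, Hoxa10 19.1, Hoxa4 16.4, Hoxa5 and Hoxa6 15, Hoxa1 12.5 and Hoxa11 5.84, and Hoxa13 had no peak. In the Hoxc cluster on chromosome 15, Hoxc9 had 25.9, Hoxc6 22.6, Hoxc8 17.5, Hoxc5 10.9, Hoxc11 9.98, Hoxc4 8.92, Hoxc10 8.36 and Hoxc12 5.79, and Hoxc13 had none. In the Hoxd cluster on chromosome 2, Hoxd3 and Hoxd4 shared a peak of fold 45.5 (74709352 to 74716926). Hoxd8 had 39.1, Hoxd9 14, Hoxd11 8.41 and Hoxd10 6.30, and Hoxd1, Hoxd12 and Hoxd13 had none. The median fold of marked members was 35.4 in paralogues 1 to 4, 32.3 in 5 to 9 and 8.36 in 10 to 13, and these medians were not tested against each other. They count the fold of a shared peak once for each gene and take the highest fold over a gene's annotated TSSs. The 45.5 of Hoxd3 and Hoxd4 lay at their annotated 5' ends (74711927 and 74711929), next to Hoxd8. Peaks further along these genes had folds of at most 15.2 (74730030 to 74741215). The 32.3 of Hoxa3 likewise lay at its 5' end (52213336), beside Hoxa7. The 15 marked genes of paralogues 5 to 9 lay under 9 distinct peaks and the 10 of paralogues 1 to 4 under 8.

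**Figure D2:**
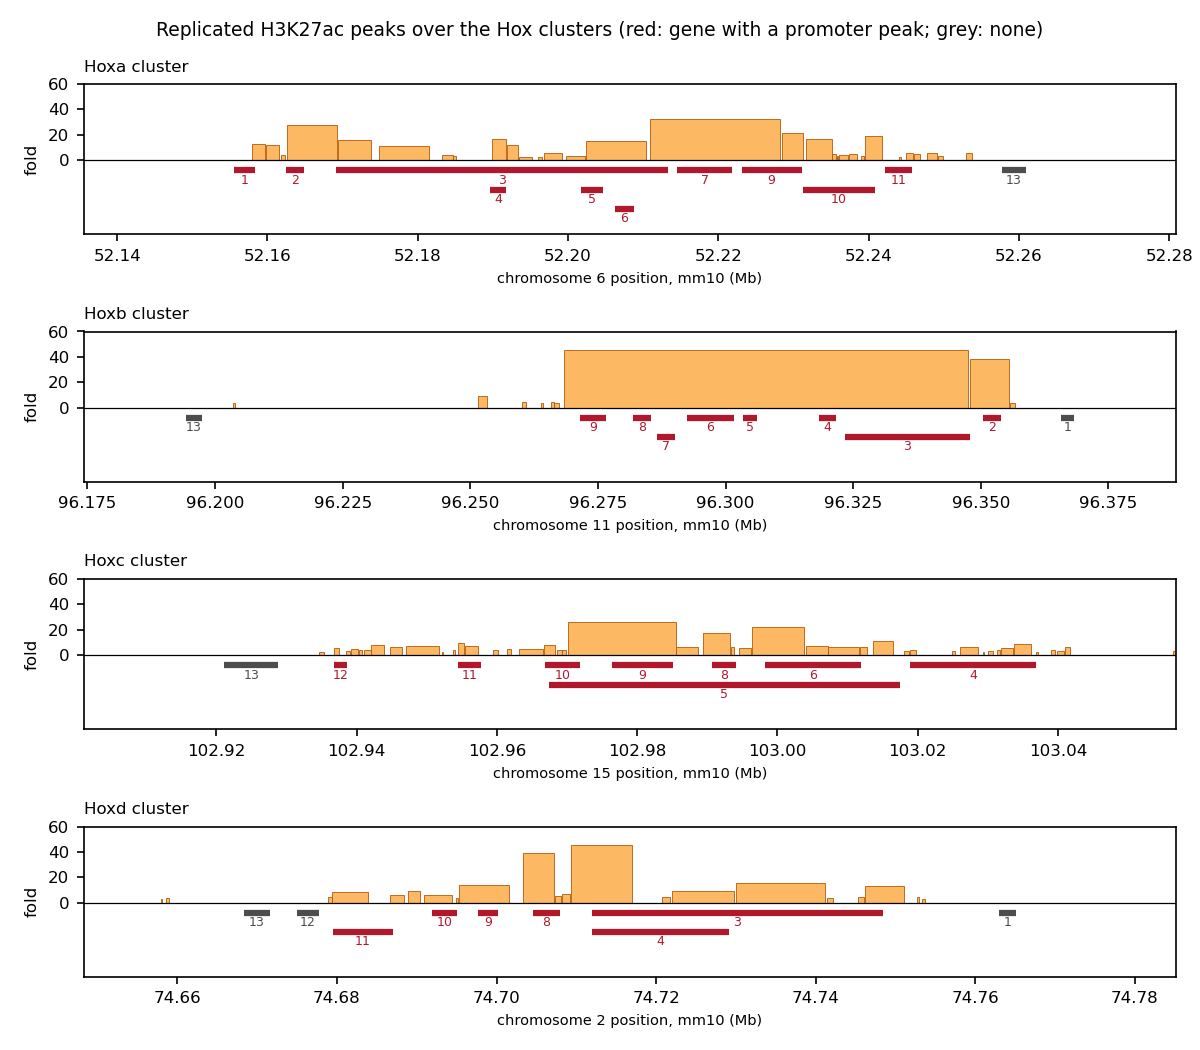
Replicated H3K27ac peaks (orange bars, height the authors' fold) over the Hoxa, Hoxb, Hoxc and Hoxd clusters by mm10 position in Mb, with each gene drawn to scale below and labelled by its paralogue number (red with a promoter peak, grey without). The peak of 79.3 kb in the Hoxb cluster has a fold of 45.1, and none of the 4 genes of paralogue 13 has a promoter peak in the replicated list.

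Distal peaks were more numerous around pan-neuronal genes and Hox paralogues 1 to 4 and 5 to 9 than in matched random lists, but not in all settings. Assigned to the nearest TSS, the mean was 1.19 distal peaks per protein-coding gene, and 15679 genes had none. Pan-neuronal genes had a mean of 10.5, against 2.57 in random lists matched on territory length (adjusted p = 0.0062, permutation, two-sided, over the 31 lists). Rbfox3 alone had 81 of their 189 peaks. Without it the mean was 6.35 against 2.39, and the call ended (adjusted p = 0.217, permutation). Here and below, random lists kept their own highest members, so leaving out the top member of a list works against a call. Whether a single gene decided a call cannot be told from it. Hox paralogues 1 to 4 had 2.75 against 0.327 (adjusted p = 0.0031, permutation), which ended without Hoxc4 (1.45 against 0.275, adjusted p = 0.126, permutation) and with random lists not matched on territory length (adjusted p = 0.459, permutation). Hox paralogues 5 to 9 had 0.933 against 0.110 (adjusted p = 0.0294, permutation), and 0.643 against 0.0886 without Hoxb9 (adjusted p = 0.0372, permutation). Their call ended when distal meant over 2500 bp from a TSS (adjusted p = 0.293, permutation). It also ended with random lists not matched on territory length (adjusted p = 1, permutation), where the difference turned negative. The Hox counts also depend on how a marked stretch was split into peaks. Most of the Hoxb cluster lay under 1 promoter peak of 79.3 kb, and Hoxb3 had 0 distal peaks. The Hoxc cluster was split into many neighbouring peaks, and Hoxc4 had 17 of the 33 distal peaks of paralogues 1 to 4. Olfactory receptor genes had fewer distal peaks, 0.0238 against 0.304 (adjusted p = 0.0031, permutation).

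Other lists did not pass this test, although several had means well above those of random lists. Hox paralogues 10 to 13 had 1.75 against 0.311 (adjusted p = 0.0788, permutation). The others were astrocyte and radial glia genes (9.23 distal peaks per gene against 2.77, adjusted p = 0.0788, permutation), neural progenitor genes (6.93 against 2.39, adjusted p = 0.127, permutation) and dorsal interneuron factors (6.33 against 1.97, adjusted p = 0.0788, permutation). Nfia led the astrocyte list with 32 distal peaks, Sox2 the progenitor list with 30 and Pax2 the interneuron list with 27. With unmatched random lists these 3 lists passed (adjusted p = 0.0103, 0.0356 and 0.0446, permutation). With replicate 1's own list the astrocyte, interneuron and Hox 10 to 13 lists did (adjusted p = 0.0381, 0.0381 and 0.0248, permutation), and with replicate 2's the Hox 10 to 13 list (adjusted p = 0.0384). Within 100 kb of the TSS the interneuron list passed (adjusted p = 0.036, permutation). Over all alternatives the highest adjusted p was 0.217 for the astrocyte and interneuron lists, 0.329 for progenitor genes and 0.806 for Hox paralogues 10 to 13. Forebrain factors had 0.8 against 2.27 (adjusted p = 0.391, permutation). The genes with the most distal peaks were Camta1 (108), the neuronal splicing regulator Rbfox1 (99), Gse1 (96), Zmiz1 (86) and Rbfox3 (81). Msi2 followed with 74, Zfhx3 with 68, the neuronal factor Myt1l with 67, Ttc28 with 62, and Auts2 and Skap1 with 58 each. Gm11146 had 57, Fyn and Maml3 55 each and Bach2 54. Of these 15 genes, Gm11146 had no promoter peak.

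Several of the highest-ranked clusters of distal acetylation lay over long non-coding RNA genes, whose own promoters count as distal here. Joining distal peaks within 10 kb of each other gave 13853 regions, of which 5421 held several peaks. Ranked by the sum of fold times length, the highest lay on chromosome 13 (83712942 to 83761268, 13 peaks, mean fold 42.0), over the long non-coding RNA genes C130071C03Rik and Gm26803. Its middle lay 84.2 kb from the TSS of Mef2c, the nearest protein-coding gene. The second (chromosome 7, 79495660 to 79558337, mean fold 20.7) was nearest to Polg and lay over Mir9-3hg. The third (chromosome 2, 30628093 to 30759449, 37 peaks) was nearest to Cstad and the fourth (chromosome 3, 88196970 to 88243437) to Rhbg. The fifth (chromosome 14, 64572513 to 64598255, mean fold 30.6) was nearest to Kif13b and lay over Mir124a-1hg. The sixth (chromosome 3, 17783787 to 17806672, mean fold 34.5) was nearest to Cypt12, 153.2 kb away, and lay over Mir124-2hg. By nearest gene the others followed as Wnt7b, the tubulin gene Tuba1a, Gpr84, Irf2bpl, Acsf3, Ncor2, Sorl1, Zmiz1, Scyl1 (over Malat1), Ythdf1, Tmem161b, Cxxc5, Lmx1b and Lhx5. The region over Lmx1b (chromosome 2, 33568255 to 33645339) held 24 peaks and that at Lhx5 (chromosome 5, 120393523 to 120441120) held 11. Both genes are factors of spinal interneurons. Counted after the ranking was seen, 9 of the 20 regions held an annotated microRNA gene. Of the 20 regions, 17 were among the 20 highest of replicate 2's own list and 16 of replicate 1's. With peaks at protein-coding promoters kept in the regions, 10 stayed among the 20 highest, and ranked by number of peaks 5 did.

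**Figure D3:**
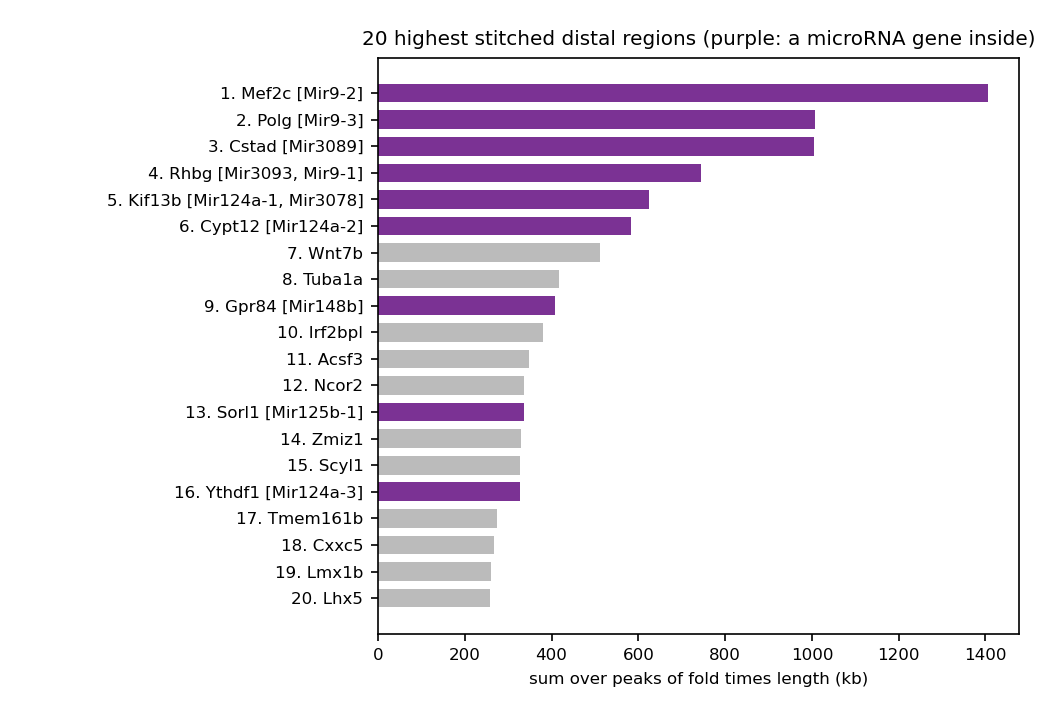
The 20 highest stitched distal regions (vertical axis, by rank, nearest protein-coding gene and, in brackets, named microRNA genes inside) against the sum over their peaks of fold times length in kb (horizontal axis). Purple bars mark the 9 regions that hold a microRNA gene, which include the 6 highest.

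Over whole distal peaks, the motifs of RFX and NFI factors had the highest ratios to matched windows, although both motifs are rare. Consensus motifs were counted in 23702 distal peaks and in as many windows of equal length and GC content (49.2% and 49.0%) 5 to 50 kb away. The RFX motif occurred 179 times in peaks and 41 times in windows, a log2 ratio of 2.13 (95% bootstrap interval over chromosomes 1.54 to 2.95). NFI factors, to which Nfia and Nfib belong, had 32 and 8 motif copies (2.00, 1.06 to 3.50). With replicate 2's own list the NFI value was 0.79, and its interval included 0. Within 200 bp around the peak summits RFX and NFI had 0.36 and 0.81, with intervals that included 0, below MEF2 at 0.98. The MEF2 motif had a log2 ratio of 0.81 (0.50 to 1.11), the homeodomain motif TAATTA 0.64 (0.58 to 0.69), the E-box CAGCTG 0.37 (0.34 to 0.40) and the Sox motif 0.33 (0.31 to 0.36). Smaller ratios were found for TEAD (0.17), GATA (0.13) and the E-box CATCTG (0.08), all with intervals above 0. On simulated sequence 10% of such intervals excluded 0 with no difference present, so they are somewhat too narrow. The E-box CATATG (-0.31, -0.37 to -0.25) and the AP-1 motif (-0.22, -0.30 to -0.13) were rarer in peaks. CTCF motifs did not differ (0.03, -0.16 to 0.24), and REST motifs were few (11 and 5).

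Some of these ratios depended on base composition. In windows not matched on GC content, TAATTA and GATA turned negative (-0.14 and -0.30). There MEF2 fell to 0.17 and Sox to 0.12, while the E-box CAGCTG rose to 0.77. Reading the letters of a motif backwards, which keeps its composition, gave 0.17 for Sox, 0.14 for GATA, -0.50 for the E-box CATCTG and -0.40 for TEAD. The reversed letters of CTCF had 2 copies in peaks and 5 in windows. The GATA ratio was no higher than that of its reversed letters. Letter orders chosen for no factor thus deviated from 0 by as much as or more than several of the motifs, so the smaller ratios do not show binding. RFX, NFI, MEF2, TAATTA and the E-box CAGCTG were not read backwards, so their larger ratios have no such control. Binding was not measured for any motif.

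**Figure D4:**
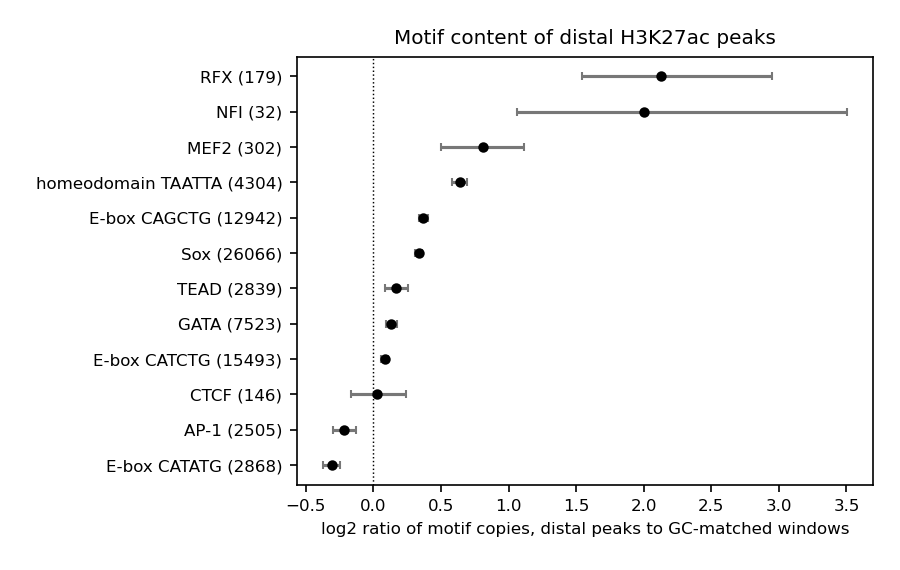
Log2 ratio of motif copies in distal H3K27ac peaks to GC-matched windows (horizontal axis) for the motifs with at least 8 copies in the windows (vertical axis, with copies in peaks). Points are the ratios and bars the 95% bootstrap intervals over chromosomes, and RFX and NFI stand highest at 2.13 and 2.00 (0.36 and 0.81 within 200 bp of the summit).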

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

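The test of distal peaks around mesenchymal and endothelial genes was chosen only after the result was seen. A signal appeared in sequence that no comparison used: 8 replicated peaks lay on scaffolds outside chromosomes 1 to 19, X and Y. The highest fold among them was 36.1, on a scaffold placed on chromosome 4 without a position (15517 to 17444). The gene tables hold only placed chromosomes, so these peaks were assigned to no gene, and no explanation was tested.

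More mesenchymal and endothelial promoters were marked in replicate 2's own list than in replicate 1's, without passing the test. Of 23 such genes, replicate 1's own list marked 6 and replicate 2's marked 12. Replicate 2's list is longer, and reduced to the 61504 peaks of smallest p it marked 8. Of the members marked in only 1 of the 2 lists, 5 were then in replicate 2's alone and 3 in replicate 1's alone. Other genes split 706 to 630, and the difference between the splits did not pass (Fisher's exact test, p = 0.729). With all peaks the members split 8 to 2 and other genes 770 to 552 (Fisher's exact test, p = 0.209). How frequent such genes were among all members and all other genes was not tested. More peaks called in replicate 2 and a difference between the tissues cannot be told apart here. The number of marked members stayed above replicate 1's without passing the test, and the power of that test with 23 genes was not simulated. Their distal peaks numbered 48 in replicate 1 and 77 in replicate 2, a ratio of 1.6, against 1.15 over all genes. In random lists matched on territory length the central 95% of ratios reached up to 1.59. The margin is narrow and the lists were picked because they differed, so more meninges and vessels in the replicate 2 tissue stays open and is not shown. The 2 pools are 1 group, so no biological explanation other than this one was tested.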

How the results depend on the processing

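The tests without the top member of each list and with the peaks found in both replicates' own lists were chosen only after the result was seen. No paired analysis was possible because there was 1 group. Of 90 alternative values of the main results, 83 kept their direction and side of the threshold or, without a test, stayed close to the main value. For counts, close meant within a fixed ratio. Of the other values of the main results, 6 moved and 1 lost its call. Of 1435 further values, 1235 were kept, 105 moved, 29 gained a call, 22 lost one and 44 reversed. A kept count can hide changed members. Unmatched random lists gave 4 lists with more distal peaks, but only 1 of the 3 main calls was among them. The 9 motifs with higher ratios fell to 6 within 200 bp of the summit, which also counted as kept. The cause of these changes was not tested.

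Each replicate's own list held more peaks than the replicated list (61504 to 68099 against 41088). Against lists matched on CpG content, 3 lists had more promoter peaks, against 5. The pooled list left Hox paralogues 1 to 9 25.9 points above 10 to 13, against 34.3 (adjusted p = 0.0601, Fisher's exact test; 0.0197 to 0.0601 over the alternatives). The replicates' own lists gave 4 to 6 lists with more distal peaks, against 3. Leaving out the top member of each list, but not of the random lists, gave 1. Of the 20 stitched regions, 10 stayed with promoter peaks kept and 5 when ranked by number of peaks.

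Among promoter shares (points above other genes), reversals were all in lists without a call. The replicates' own lists ranged from -7.88 to 6.49 for ventral progenitor TF, -7.37 to 11.6 for ventral interneuron TF, -4.03 to 19.96 for motor neuron, -24.0 to 4.95 for endothelium and -4.03 to 11.6 for proliferation. The 50% of peaks of highest fold gave -29.9 for motor neuron, -26.6 for oligodendrocyte precursor and -4.91 for proliferation. A −log10 q of at least 5 gave -31.8, -18.4 and -6.75, and peaks in both replicates' own lists -8.82, -0.48 and -0.48 for the same 3. Matching on CpG content gave -2.53 for dorsal interneuron TF, -18.3 for Hox paralogues 10 to 13, 1.97 for microglia and macrophage and -19.6 for proliferation.

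Among distal peaks (mean per gene above random lists), unmatched lists reversed dorsal progenitor TF (0.151), ventral progenitor TF (0.193), ventral interneuron TF (1.26), motor neuron (0.0525), excitatory transmission (1.58), Hox paralogues 5 to 9 (-0.265), meninges and mesenchyme (0.501), cartilage and sclerotome (0.0766), skeletal muscle (-0.196), endothelium (0.224) and housekeeping (-0.059). Of these, Hox paralogues 5 to 9 had a call. Peaks within 100 kb reversed ventral interneuron TF (0.274), microglia and macrophage (-0.111) and proliferation (-0.0822). Leaving out the top member reversed dorsal root ganglion and neural crest (-0.227), skeletal muscle (-0.0265) and proliferation (-0.332). The replicates' own lists ranged from -0.209 to 0.299 for skeletal muscle. The 50% of highest fold gave 0.169 and peaks in both own lists 0.00873 for germ line and pluripotency.

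Among motifs (log2), unmatched windows, which are poorer in GC (45.3% against 50%), reversed TAATTA (-0.14) and GATA (-0.30). CTCF reversed within 200 bp of the summit (-0.62), in the 50% of highest fold (-0.093) and in the replicates' own lists (-0.20 to -0.15). Without read counts, what depth limits could not be measured.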

Other observations

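The test that left out promoters of long non-coding RNA genes was chosen only after the result was seen, as were the microRNA families named and the requirement that the interval of the X-linked fold ratio hold 0.75. Of 10143 long non-coding RNA genes, 947 (9.34%) had a replicated peak within 1 kb of a TSS and away from protein-coding promoters. The highest folds were at C130071C03Rik and Gm26803 (58.4), Malat1 (56.3), 1810026B05Rik (52.3), Mir124-2hg (48.0) and Mir124a-1hg (44.7). After the peak over Hoxb genes, the widest peaks at protein-coding promoters outside the Hox clusters lay at Zfhx3 (13.6 kb), Tnrc18 (13 kb), Meis1, a Hox cofactor (12.3 kb), Ebf3 (11.7 kb), and Zic1 and Zic4, dorsal neural factors (11.4 kb).

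Of the 20 highest stitched distal regions, 9 held a microRNA gene. Mir9-2, Mir9-3 and Mir9-1 lay in the regions ranked 1, 2 and 4, and Mir124a-1, Mir124a-2 and Mir124a-3 in those ranked 5, 6 and 16. MicroRNAs miR-9 and miR-124 act in neural progenitors and neurons. Random regions of like span held one in a mean of 1.07 of 20 (central 95% up to 3), which argues against the explanation that long regions hold more genes of any kind. With peaks at protein-coding and long non-coding RNA TSSs left out, 1 of the 20 highest regions held a microRNA gene (random mean 0.947). That test is void, because 11 of the 12 microRNA genes in the regions lie inside the peaks left out. Leaving out peaks at any TSS also gave 1 and is void too, because the TSSs of the microRNA genes were themselves among those left out. Promoters of long non-coding RNA genes, or of other non-coding genes, counted as distal thus stay open as explanations. There was 1 group, so no biological explanation was tested.

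Genes on the X chromosome had fewer promoter peaks. Of 948 X-linked genes 342 (36.1%) had one, and of 20780 autosomal genes 11214 (54.0%). The replicates' own lists gave 35.7% and 39.1% for X-linked and 55.3% and 56.3% for autosomal genes. Distal peaks numbered 1.33 per Mb on X and 10.5 on the autosomes. Autosomal lists matched on CpG content had a mean of 42.8% (central 95%, 40.3% to 45.5%), which argues against CpG content of the promoters as the whole cause. The promoter folds of X-linked genes were 0.888 times those of CpG-matched autosomal genes (95% interval 0.821 to 0.963). A pool of as many males as females holds 0.75 X copies per autosomal copy, which lies outside that interval. That value counts copies of the chromosome, and how many of them carry the mark is not known here. The criterion written before the result was seen asked for an interval under 1 whose upper bound reaches 0.75. The interval meets it, but so would nearly any ratio under 1. Weaker peaks are not listed, so the ratio is set in part by the peak threshold, and whether the fold corrects for copy number is unknown. The test therefore leaves fewer X copies undecided. Over genes with a promoter peak, the median fold was lower on X (7.10) than on the autosomes (9.28). Over all peaks, promoter and distal, the median fold was higher on X (5.62) than on the autosomes (4.23). Distal peaks, which had lower folds, made up 1.33 of 3.84 peaks per Mb on X and 10.5 of 16.4 on the autosomes. The median over all peaks thus mixes different shares of promoter and distal peaks. The mappability of X was not tested. The sexes were pooled, so no biological explanation was tested.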
